A study of Mus musculus with 6 samples.

How the data were processed

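RNA was sequenced from mouse muscle stem cells cultured for 24 h with prostaglandin E2 (PGE2) or with DMSO as Vehicle, in 6 libraries, 3 per group. Per the labels' protocols, the cells were sorted by flow cytometry from hindlimb muscles of young adult female C57BL/6 mice as cells with α7-integrin and CD34 and without CD45, Sca1, CD31 and CD11b, and were kept in a medium with fetal bovine serum. RNA was extracted with a Qiagen micro-scale kit and the cDNA was amplified with a NuGEN Ovation kit before Illumina library construction, per the labels' protocols. The submitters' processing notes name STAR, RSEM and the build mm10; versions, settings and the annotation release are not given in the sources used here. The labels call the libraries biological replicates and do not say whether they came from separate animals, sorts or cultures, so a p-value here measures the spread between these libraries, which may be technical in part.

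The values the authors deposited are TPM, a transcript's share of a library after correction for its length, in 1 table with 1 column per library. No header names the unit: it was inferred from the values, which carry 2 decimals and sum to between 992357 and 995645 per library. TPM keeps no read depth, so the depth of each library is unknown and no interval that needs it is given. The table holds 43283 gene identifiers paired with symbols. Of these, 42782 were found in the GENCODE M21 annotation of the same build, which gave positions and gene types. An exact 0 in such a table can be a failed estimate. None of 13 housekeeping genes checked was at 0 in any library. Genes at 0 throughout a group are described as listed at 0 and given no fold change. No 2 libraries held identical values.

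The design written before the data were examined named a count test and, for a table of normalized values, limma on log2(TPM + 1); since the table holds TPM, the latter was used. Genes with 1 TPM or more in at least 3 libraries were kept, which left 12781, and PGE2 was compared with Vehicle with limma 3.58.1 in R 4.3.3 (variance prior with a mean trend, not robust), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. All tests were two-sided. Log2 changes are PGE2 minus Vehicle on the log2(TPM + 1) scale, which understates the change of low genes. Intervals are 95% confidence intervals of the limma fit.

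Also fixed before the data were examined were 31 gene lists, holding 671 entries of which 669 matched a symbol in the table. They were tested with limma's camera (preset inter-gene correlation of 0.01), which compares a list with all other tested genes, with Benjamini-Hochberg adjustment over the 30 lists with 3 or more tested members. The alternative fry asks only whether the genes of a list move, on balance, one way, without comparing them with other genes. Members were also adjusted over the list alone.

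The genes named were set by a rule made at the same time. It takes genes past the threshold with a mean of 5 TPM or more and no overlap between the groups (10 per direction), 14 fixed genes, up to 4 members with the smallest p per list described (here those with an unadjusted p under 0.1), and, where fewer than 5 genes pass in a direction, the 5 with the smallest p. Because no gene passed, a further rule was added after the values were seen, which takes protein-coding genes by the first criterion with an unadjusted in place of an adjusted p. Of the genes that rule takes, 1 is not reported here. Crem, Ptprc, Laptm5, Pecam1, Col3a1, Ly6a and mt-Co3 fall outside these rules and were chosen as examples after their values were seen.

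The tests were checked on simulated data with the mean and the pooled residual SD of each gene in the real libraries. The simulated spread was thus equal in both groups. Of 200 genes changed among the 12781, 0% were recovered at a log2 change of 1, 21% at 2 and 80% at 3. The changed genes were drawn from those with a mean log2(TPM + 1) at or above its value at 5 TPM. A shift of 0.5 in the cAMP and CREB list was recovered by camera in 46 of 50 simulations, with 3 calls of other lists. The simulated noise was independent between genes, so these counts do not show how camera behaves where the members of a list correlate. The shift was also larger than the mean change of that list in the real data (0.33). Alternatives covered the pseudocount, the filter, the scaling, the variance prior, library weights, the replicate number as a block, each library left out in turn, and the list test; those that need read counts were not run. Python 3.11.15 was used for tables and figures.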

Results

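Gene expression was measured by RNA sequencing in cultured mouse muscle stem cells, the Pax7-positive cells from which muscle regenerates, after 24 h with PGE2, a lipid mediator released in injured tissue, or with DMSO. Each group had 3 libraries. The number of genes listed above 0 was 19677, 18201 and 16446 in Vehicle 1 to 3 and 15400, 16558 and 17710 in PGE2 1 to 3. Mitochondrial genes held 20.9%, 28.3% and 33.6% of the TPM in the Vehicle libraries and 23.0%, 25.5% and 30.4% in the PGE2 libraries. Read depth was unknown, since TPM does not keep it. The series asks, by its title, what PGE2 does for the function of these cells, and the comparison addresses which transcripts differed after a day of exposure.

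Targets of cAMP and CREB, the signalling route downstream of the PGE2 receptors EP2 and EP4, rose as a group with PGE2 (16 of 24 tested members higher), and genes of muscle differentiation fell as a group (13 of 17 lower). Both calls were made at camera's preset correlation and were lost with an estimated correlation, a setting in which camera also uses fewer degrees of freedom (Benjamini-Hochberg adjusted p = 0.48 each). A count of 2 lists was also not particular to the real grouping. It was reached by 3 of the 10 splits of the 6 libraries, the real one included. No single gene passed the threshold. The orphan nuclear receptor Nr4a2, an immediate CREB target, was at 12.9 ± 4.87 TPM in Vehicle and 34.5 ± 6.98 TPM in PGE2 (mean ± SD, n = 3 each). The sarcomere gene Ttn, which encodes titin, was at 25.9 ± 16.0 TPM in Vehicle and 8.47 ± 3.14 TPM in PGE2 (mean ± SD, n = 3 each). The stem cell and myoblast regulators Pax7, Myf5 and Myod1 and the proliferation marker Mki67 had overlapping values in both groups.

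**Figure D1:**
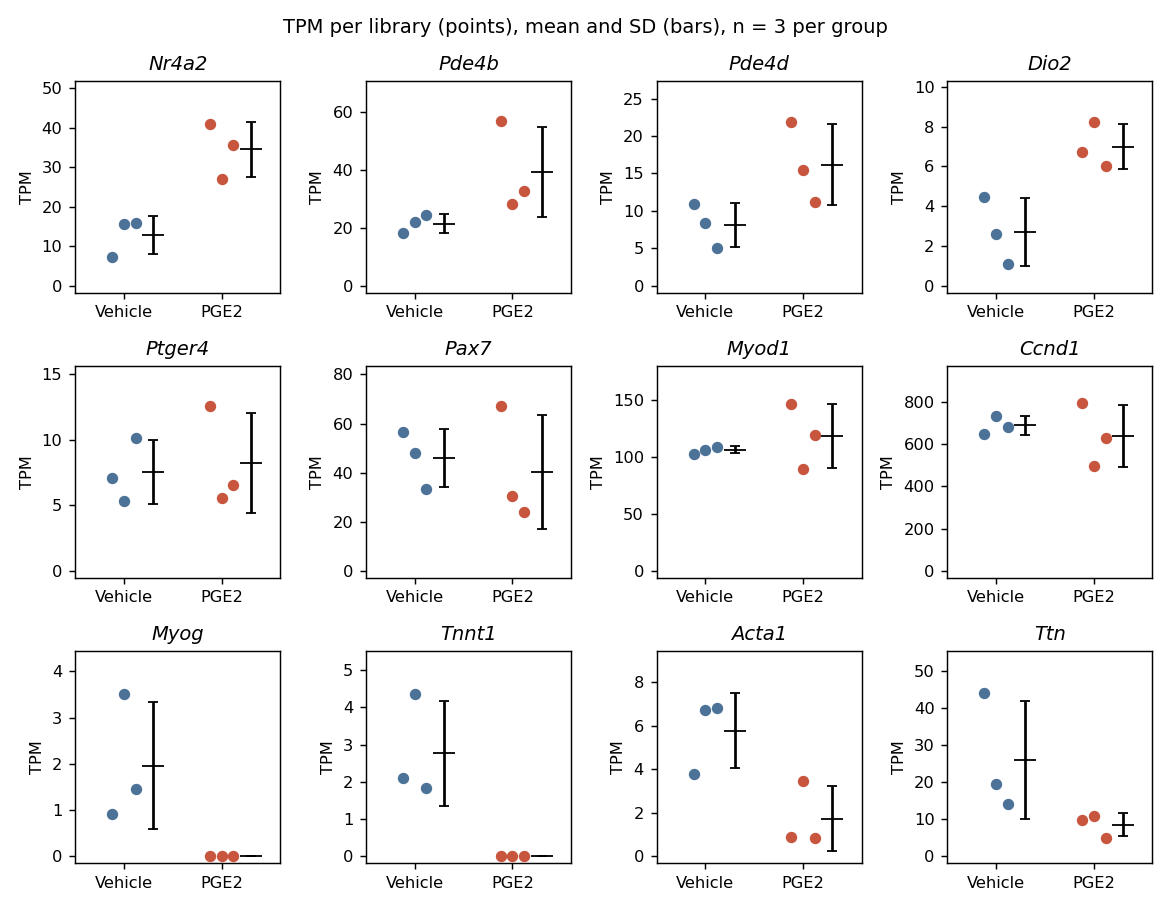
TPM of 12 genes in each library (points; Vehicle blue, PGE2 red), with the mean and SD of 3 libraries per group beside them (horizontal and vertical bars). Nr4a2, Pde4b, Pde4d and Dio2 were higher in every PGE2 library than in every Vehicle library, and Myog, Tnnt1, Acta1 and Ttn were lower. Ptger4, Pax7, Myod1 and Ccnd1 overlapped. Myog was too low to test, and none of the other genes shown passed the test over all genes.

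Of the 28 cAMP and CREB targets, 24 were tested, 16 with a higher and 8 with a lower fitted value with PGE2, and their median log2 change was 0.38. The list rose relative to all other genes by limma's camera (p = 0.00221, Benjamini-Hochberg adjusted p = 0.0332), and the call was lost at an adjusted p = 0.48 with an estimated correlation. None of the 24 members passed the limma test over all genes or adjusted over the list alone, where the smallest Benjamini-Hochberg adjusted p was 0.161. Nr4a2 (ENSMUSG00000026826, mm10 chromosome 2, 57106830 to 57124003, minus strand) read 7.31, 15.6 and 15.9 TPM in Vehicle 1 to 3 and 40.9, 27.1 and 35.6 TPM in PGE2 1 to 3. Its log2 change was 1.40 (95% confidence interval 0.48 to 2.32), a 2.64-fold difference on the log2(TPM + 1) scale. Nr4a2 had a Benjamini-Hochberg adjusted p of 1.00 over all genes and 0.0538 over the fixed genes alone in limma. Pde4b and Pde4d, phosphodiesterases that break down cAMP, were higher in each PGE2 library than in each Vehicle library without passing the test. Pde4b read 18.1, 21.9 and 24.4 TPM in Vehicle and 56.8, 28.01 and 32.8 TPM in PGE2. Pde4d read 10.9, 8.34 and 4.99 TPM in Vehicle and 21.9, 15.4 and 11.2 TPM in PGE2. Dio2, the enzyme that activates thyroid hormone, read 4.48, 2.61 and 1.08 TPM in Vehicle and 6.73, 8.22 and 6.02 TPM in PGE2. Other members overlapped between the groups. The CREB family gene Crem, for example, read 4.44, 15.9 and 25.3 TPM in Vehicle and 17.1, 6.15 and 7.46 TPM in PGE2. The adjusted camera p became 0.213, 0.0987, 0.134, 0.243 and 0.164 without Vehicle 1, Vehicle 2, PGE2 1, PGE2 2 and PGE2 3 in turn. By fry it was 0.435.

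Of the 37 muscle differentiation genes, 17 were tested, 13 with a lower and 4 with a higher fitted value with PGE2, with a median log2 change of -0.37. The list fell relative to all other genes by limma's camera (p = 0.00202, Benjamini-Hochberg adjusted p = 0.0332), and the call was lost at an adjusted p = 0.48 with an estimated correlation. None of the 17 members passed the limma test over all genes or adjusted over the list alone, with a smallest Benjamini-Hochberg adjusted p of 0.108. Ttn read 44.2, 19.6 and 14.1 TPM in Vehicle and 9.71, 10.8 and 4.90 TPM in PGE2. Acta1, the skeletal muscle actin, read 3.79, 6.71 and 6.82 TPM in Vehicle and 0.90, 3.47 and 0.81 TPM in PGE2. Tnnt1, the slow-fibre troponin T, read 2.09, 4.37 and 1.82 TPM in Vehicle and was listed at 0 in the PGE2 libraries. Cdkn1a, which encodes the cell cycle inhibitor p21 and is also a p53 target, read 142, 249 and 289 TPM in Vehicle and 61.9, 119 and 222 TPM in PGE2. Most terminal genes were near 0 in both groups and untested. Myog, the transcription factor of differentiation, read 0.91, 3.52 and 1.45 TPM in Vehicle and was listed at 0 in the PGE2 libraries. More protein-coding genes of all kinds were listed at 0 in every PGE2 library and above 0 in every Vehicle library (123) than the other way round (38). The same count for other choices of 3 libraries ran from 14 to 146. The adjusted camera p of the differentiation list became 0.307, 0.0653, 0.375, 0.0694 and 0.164 without Vehicle 2, Vehicle 3, PGE2 1, PGE2 2 and PGE2 3 in turn. It was 0.0544 after quantile normalization and 0.162 by fry.

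**Figure D2:**
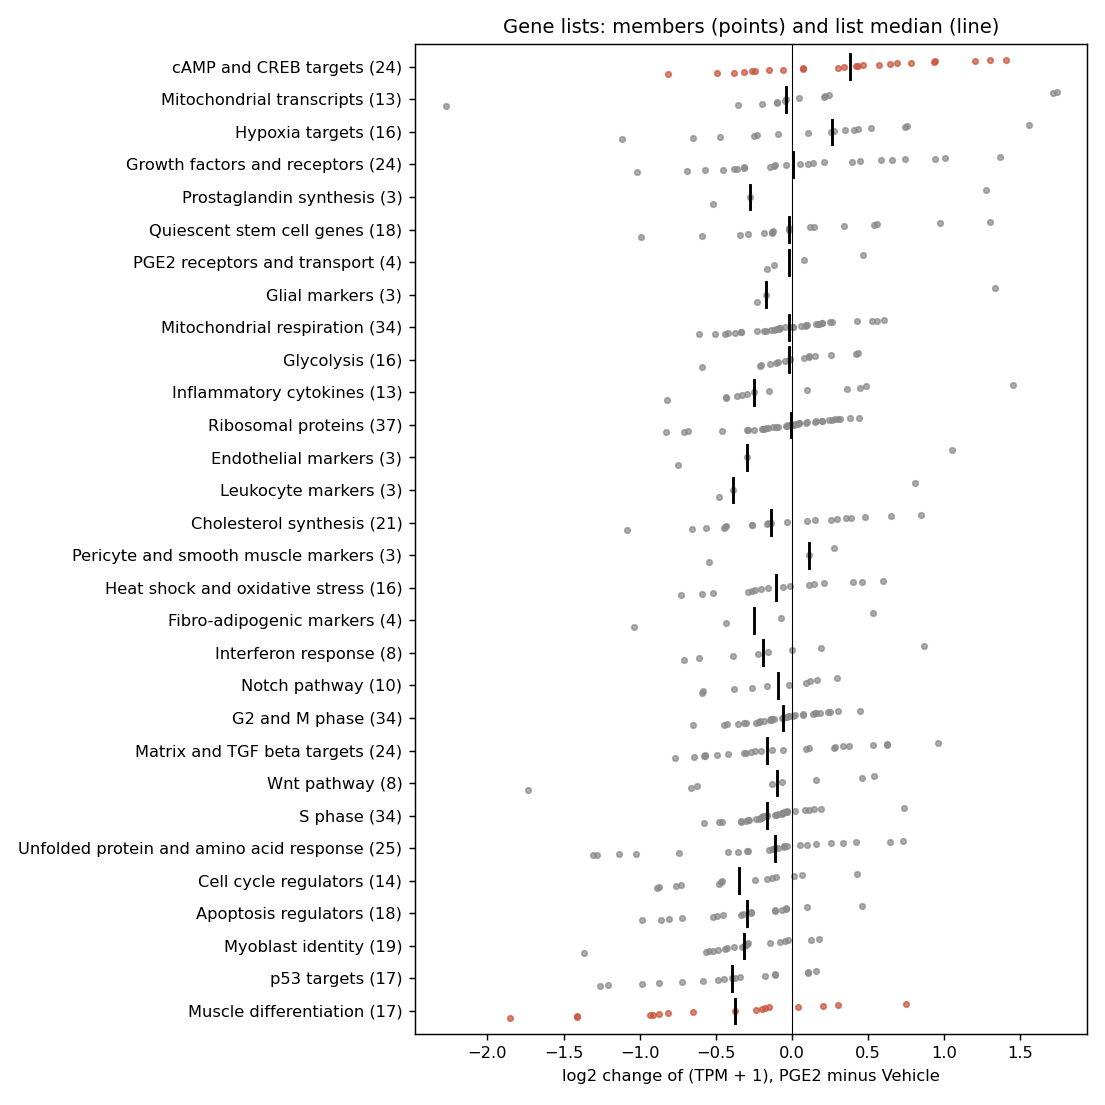
Fitted log2 change of (TPM + 1), PGE2 minus Vehicle, of the tested members of each gene list (points, number of members in brackets) with the list's median (vertical bar), sorted by camera's direction and p. The lists past the threshold (red) were cAMP and CREB targets, with a median of 0.38, and muscle differentiation, with a median of -0.37. Both calls were lost with an estimated correlation, a setting in which camera also uses fewer degrees of freedom.

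Among the PGE2 receptors, Ptger4, which encodes EP4, was expressed at 7.50 ± 2.44 TPM in Vehicle and 8.23 ± 3.80 TPM in PGE2 (mean ± SD, n = 3 each). Its log2 change of 0.08 (95% confidence interval -1.04 to 1.21) turned negative without Vehicle 2 or without PGE2 1. The other receptors were too low to test. Ptger1 reached 2.43 TPM and Ptger3 1.88 TPM in 1 library each, and Ptger2 stayed at or below 0.12 TPM in all 6 libraries. Slco2a1, the prostaglandin importer, was at 2.78 ± 0.83 and 2.63 ± 1.43 TPM in Vehicle and PGE2 (mean ± SD, n = 3 each). The PGE2-degrading enzyme Hpgd stayed at or below 0.78 TPM. Ptgs2, the inducible cyclooxygenase, read 0.20, 0.27 and 0 TPM in Vehicle and 0.27, 2.69 and 1.94 TPM in PGE2 and was untested. Ptgs1, the constitutive cyclooxygenase, read 5.46, 8.43 and 7.06 TPM in Vehicle and 36.0, 14.6 and 11.1 TPM in PGE2. It had a limma p of 0.0312 before adjustment and a Benjamini-Hochberg adjusted p of 0.0936 over the list alone.

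The fixed stem cell and proliferation genes overlapped between the groups and did not pass the test. Pax7, the marker of muscle stem cells, was at 46.0 ± 11.8 TPM in Vehicle and 40.4 ± 23.2 TPM in PGE2 (mean ± SD, n = 3 each), with the PGE2 libraries at 67.0, 30.3 and 23.9 TPM. Of the myogenic regulators, Myf5 was at 279.8 ± 26.5 and 202.1 ± 92.0 TPM and Myod1 at 106.1 ± 3.12 and 118.3 ± 28.4 TPM in Vehicle and PGE2 (mean ± SD, n = 3 each). Ccnd1, the G1 cyclin, was at 688 ± 43.8 and 639 ± 147.5 TPM and Mki67 at 144 ± 43.7 and 153 ± 102 TPM in Vehicle and PGE2 (mean ± SD, n = 3 each). The log2 changes were -0.29 (95% confidence interval -1.24 to 0.66) for Pax7, -0.56 (-1.36 to 0.23) for Myf5, 0.13 (-0.52 to 0.78) for Myod1, -0.13 (-0.80 to 0.54) for Ccnd1 and -0.06 (-1.05 to 0.92) for Mki67. The sign turned without PGE2 3 for Pax7, without PGE2 1 for Myod1, without PGE2 2 for Ccnd1. For Mki67 it turned without Vehicle 1, PGE2 2 or PGE2 3 and after median-ratio scaling or quantile normalization. Myf5 kept its sign, with a log2 change of -0.24 without PGE2 1 and -0.90 without PGE2 3. Of the 14 fixed genes, 8 were tested and 0 passed limma's test, either over all genes or adjusted over the list alone. Of them 1, Nr4a2, had an unadjusted p under 0.05.

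Neither S phase genes (6 of 34 higher, median log2 change -0.16) nor G2 and M phase genes (12 of 34 higher, median -0.06) passed camera, each with a Benjamini-Hochberg adjusted p of 0.942. Another 4 lists had mostly lower values and missed camera's threshold. Some share members: Cdkn1a is in the p53, cell cycle and differentiation lists, and Pmaip1 is in the p53 and apoptosis lists. The apoptosis and cell cycle lists hold both genes that promote and genes that restrain the process. Of the p53 targets 14 of 17 were lower (median -0.40, limma camera Benjamini-Hochberg adjusted p = 0.0654). Pmaip1, which encodes the pro-apoptotic protein Noxa, read 13.0, 24.8 and 21.8 TPM in Vehicle and 5.56, 11.9 and 11.5 TPM in PGE2. The p53 list passed without a filter (0.0382), with a filter of 5 TPM (0.0108) and with a mean-variance trend in camera (0.0268), all at the preset correlation. With an estimated correlation its adjusted p was 0.48. Btg2, an antiproliferative p53 target, read 4.98, 7.82 and 11.4 TPM in Vehicle and 1.78, 6.63 and 1.23 TPM in PGE2. Of the myoblast identity genes 17 of 19 were lower (median -0.31, adjusted p = 0.197 by the same test). Of the apoptosis regulators 16 of 18 were lower (median -0.30, adjusted p = 0.207), and of the cell cycle regulators 11 of 14 (median -0.35, adjusted p = 0.207). Apoptosis regulators passed by fry, which does not compare them with other genes (adjusted p = 0.0202), and the identity and cell cycle lists passed without a filter (0.0382 each). All 3 had an adjusted p = 0.48 in camera with an estimated correlation. Pax3, a myogenic transcription factor, read 5.70, 8.23 and 2.37 TPM in Vehicle and 0.93, 2.72 and 0.70 TPM in PGE2. The retinoblastoma gene Rb1 read 31.6, 48.5 and 29.5 TPM in Vehicle and 19.9, 22.4 and 19.7 TPM in PGE2. Cdkn2c, which encodes a CDK4 and CDK6 inhibitor, read 28.3, 20.2 and 15.0 TPM in Vehicle and 7.35, 12.6 and 12.8 TPM in PGE2.

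In the other lists, Lef1, a transcription factor of the Wnt pathway, read 8.49, 17.5 and 13.6 TPM in Vehicle and 3.19, 1.59 and 5.42 TPM in PGE2. It had a log2 change of -1.73 and a limma Benjamini-Hochberg adjusted p of 1.00 over all genes and 0.0757 adjusted over the list alone. Gclm, a subunit of the enzyme that starts glutathione synthesis, was at 718 ± 111 TPM in Vehicle and 438 ± 112 TPM in PGE2 (mean ± SD, n = 3 each). The chemokine gene Cxcl2 was listed at 0 in Vehicle and read 2.03, 2.28 and 1.06 TPM in PGE2. Neither passed adjusted over its list alone (0.663 and 0.245, limma with Benjamini-Hochberg). Spry1, a growth factor signalling inhibitor of quiescent muscle stem cells, read 13.9, 14.6 and 19.1 TPM in Vehicle and 13.6, 4.96 and 5.77 TPM in PGE2. The metabolic genes Cth, of cysteine synthesis, and Pmvk, of the mevalonate pathway, had values of 41.4, 23.1 and 47.2 TPM and 2.37, 2.79 and 1.78 TPM in Vehicle. In PGE2 they read 7.49, 51.1 and 6.40 TPM and 0, 1.31 and 0.61 TPM. By camera with Benjamini-Hochberg adjustment, the adjusted p was 0.501 for mitochondrial transcripts, 0.627 for hypoxia targets, 0.948 for the interferon response and 0.970 for cholesterol synthesis and for heat shock and oxidative stress. It was 0.942 for PGE2 receptors and transport, prostaglandin synthesis, quiescent stem cell genes, the Notch and Wnt pathways, inflammatory cytokines, matrix and TGF beta targets, growth factors and receptors, glycolysis, mitochondrial respiration, the unfolded protein and amino acid response, and ribosomal proteins. In 13 lists, none of them past the threshold, the median, the mean and camera's direction differed in sign. Ribosomal proteins, for example, had a median of 0.00, a mean of -0.04 and the direction up.

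Markers of the other cell types a muscle sort could hold were mostly too low to test, and the tested members went both ways. Endothelial, leukocyte, glial and pericyte and smooth muscle lists had 3 tested members each, the fibro-adipogenic list 4 and the red cell list 0. Camera's Benjamini-Hochberg adjusted p was 0.942 for endothelial, leukocyte and glial markers and 0.970 for the fibro-adipogenic and the pericyte and smooth muscle markers. The leukocyte gene Ptprc, which encodes CD45, read 4.19, 0.81 and 0.45 TPM in Vehicle and 1.80, 3.47 and 4.81 TPM in PGE2, and was the only 1 of the 3 tested leukocyte markers with a higher fitted value. Laptm5, another leukocyte gene, read 2.93, 5.50 and 0.83 TPM in Vehicle and 6.45, 0 and 1.32 TPM in PGE2. The endothelial gene Pecam1, which encodes CD31, stayed at or below 1.55 TPM. Eng, another endothelial gene, read 1.57, 1.10 and 0.96 TPM in Vehicle and 2.55, 6.44 and 2.54 TPM in PGE2. Col3a1, a collagen of fibro-adipogenic cells, read 15.3, 28.1 and 20.2 TPM in Vehicle and 36.5, 30.4 and 24.9 TPM in PGE2, and the other 3 tested fibro-adipogenic markers had lower fitted values. Of these, Ly6a, which encodes Sca1, read 2.22, 3.38 and 7.92 TPM in Vehicle and 0, 13.55 and 0 TPM in PGE2.

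Of the 13 mitochondrial mRNAs, mt-Atp6 and mt-Co2 passed adjusted over the list alone (limma, Benjamini-Hochberg adjusted p = 0.0218 for mt-Atp6, the smallest) and not over all genes (0.613 and 1.00). mt-Atp6 was at 1218 ± 295.5 TPM in Vehicle and 4136 ± 1666 TPM in PGE2 (mean ± SD, n = 3 each). mt-Co2 was at 1510 ± 800.2 and 4658 ± 1492 TPM (mean ± SD, n = 3 each). Both genes are identical in sequence to nuclear copies on chromosome 1 that are also in the table. Summed with the copy they had log2 changes of 0.07 ± 0.46 and 0.15 ± 0.43 (± SE), and of 0.36 and 0.42 without PGE2 1. The mitochondrial list passed camera without PGE2 1 at the preset correlation (adjusted p = 0.00674). Over all 6 libraries it had an adjusted p = 0.983 with an estimated correlation.

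**Figure D3:**
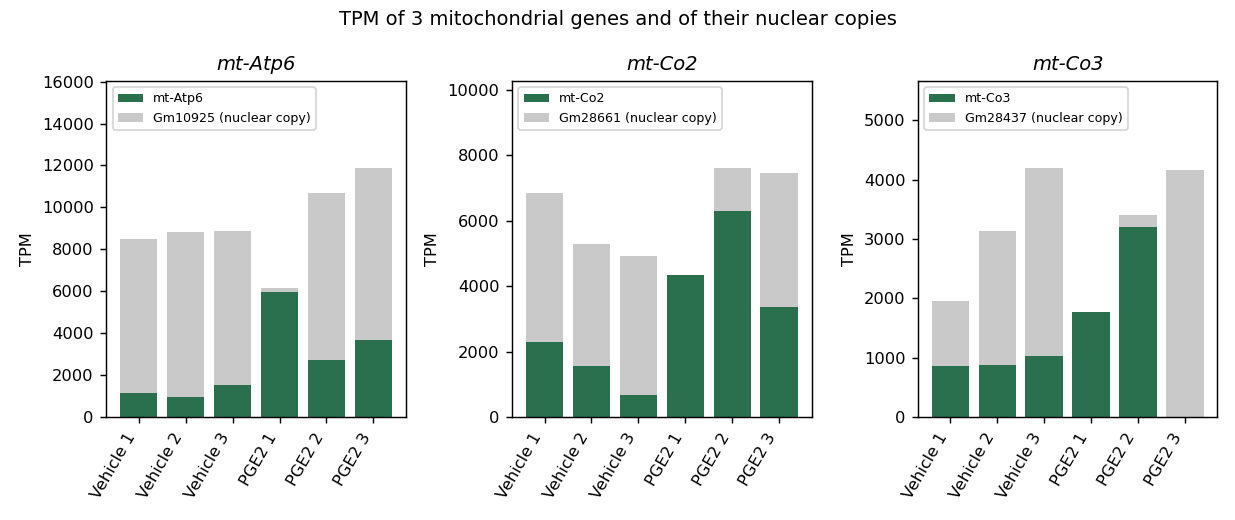
TPM of mt-Atp6, mt-Co2 and mt-Co3 (green) stacked on that of their nuclear copies (grey) in each library, each bar starting at 0. The mitochondrial gene held a larger part of the sum in PGE2 1 and PGE2 2 than in any Vehicle library for all 3 genes, and in PGE2 3 it was at 0.21 TPM for mt-Co3.

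Over all 12781 genes, 0 passed limma's test at a Benjamini-Hochberg adjusted p under 0.05, and 464 (3.63%, where chance gives 5%) had an unadjusted p under 0.05, 201 higher and 263 lower with PGE2. That count was 979 (7.66%) without PGE2 1 and 758 (5.93%) without PGE2 3. The groups did not overlap for 1024 genes (8.01%, where chance gives 10% for 3 against 3). The smallest adjusted p, 0.0704, was shared by 8 genes, all with lower values in PGE2. Of these, 7 are short noncoding genes or pseudogenes listed at 0 in the PGE2 libraries, among them Gm11522, n-R5-8s1, Gm22077 and Gm12013. The protein-coding one was Tceanc2 (chromosome 4, 107134155 to 107179116), a gene with a transcription elongation factor domain, which read 45.1, 38.9 and 16.2 TPM in Vehicle and 0.92, 1.67 and 0.26 TPM in PGE2. Among genes with higher values in PGE2, the smallest p belonged to Gm11575, Gm10335, Gm6421, Gm24157 and Gm9115, none of which passed the test (smallest adjusted p = 0.360). Of these, Gm11575, Gm6421 and Gm24157 were listed at 0 in the Vehicle libraries, and Gm10335 read 16.4, 0 and 0 TPM there. Gm9115, a pseudogene, read 3.19, 7.91 and 10.2 TPM in Vehicle and 33.4, 43.1 and 28.2 TPM in PGE2. With a robust variance prior, 1 gene passed, Gm11522 (adjusted p = 0.0431). Leaving out 1 library gave 1 gene without Vehicle 1, PGE2 1 or PGE2 2, 2 genes without PGE2 3 and 0 without Vehicle 2 or Vehicle 3.

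The PGE2 libraries differed more from each other than the Vehicle libraries did. Pearson's r of log2(TPM + 1) across genes was 0.807 to 0.846 between PGE2 libraries, 0.886 to 0.926 between Vehicle libraries and 0.833 to 0.897 between the groups. Over 8370 genes with a mean of 5 TPM or more, the median SD on the log2 scale was 0.588 in PGE2 and 0.366 in Vehicle, and the median half-width of the 95% confidence interval was 1.02, a 2.03-fold difference. The simulated data gave each gene its pooled SD in both groups, and so not the wider spread of the PGE2 libraries. There the test recovered 0% of genes changed by 1 on the log2 scale, 21% of those changed by 2 and 80% at 3. The changed genes had a mean log2(TPM + 1) at or above its value at 5 TPM, and lower genes were not simulated as changed. In that simulation most differences of 2 or less on the log2 scale were thus not detected in single genes of that level.

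**Figure D4:**
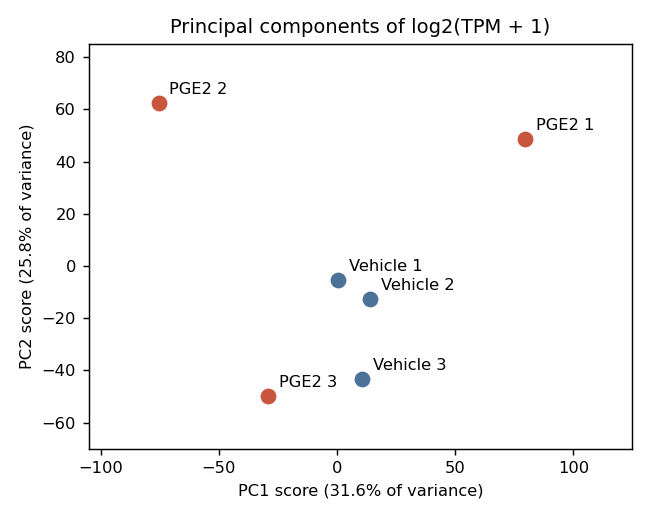
Scores of the 6 libraries on the first principal components of log2(TPM + 1), which hold 31.6% (PC1) and 25.8% (PC2) of the variance. PGE2 1 and PGE2 2 lie at opposite ends of PC1 (79.6 and -75.5), and PC1 does not part the groups.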

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

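Chosen after the data were seen were the filter of 5 TPM, the restriction to protein-coding genes, library weights, the robust variance prior, the 3 other scalings and camera's mean-variance trend, and for the lists also the pseudocount of 0.1 and the missing filter. Alternatives that need counts (other size factors, other count tests, voom) were not run, because the table holds TPM. The count of changed genes, 0 by limma with 464 at an unadjusted p under 0.05, was 0 under every alternative except a robust variance prior (1 gene, Gm11522) and some fits without 1 library (0 to 2 genes). The unadjusted count ran from 257 (filter of 5 TPM) to 979 (without PGE2 1), with 758 without PGE2 3. The median change of all genes was -0.07, and -0.10 with a pseudocount of 0.1, -0.12 with library weights and -0.17 without PGE2 1. Changes are printed as fitted, without subtracting it. The labels do not say whether the replicate number pairs the libraries, and the values showed no sign of it, which does not exclude it. Deviations of same-numbered libraries correlated at -0.06, -0.04 and 0.07, and 2 of 6 libraries correlated best with their own number. With a replicate block 0 genes passed by limma (482 at an unadjusted p under 0.05) and 2 lists passed, and it changed no call. The number of lists past the threshold was 2, and 5 without a filter, 3 with a filter of 5 TPM or a mean-variance trend, 1 after quantile normalization, 0 with an estimated correlation, 1 by fry and 0 to 1 without 1 library. For the cAMP and CREB list the adjusted p was 0.48 with an estimated correlation, 0.435 by fry and 0.0108 to 0.243 without 1 library. For the differentiation list it was 0.0544 after quantile normalization, 0.48 with an estimated correlation, 0.162 by fry and 0.00711 to 0.375 without 1 library. Both kept their direction in every setting run. Fewer libraries were left in the fits without 1; otherwise the cause was not tested. Of 903 values of 58 named genes over 16 settings, 888 kept their direction and side of the threshold. The others were 3 that passed (Gm10335 without Vehicle 1, Gm24157 without PGE2 3, Gm11522 with a robust prior) and 12 that turned in sign, all of genes far from the threshold. The count of 888 was in part fixed in advance. A changed filter, the restriction to protein-coding genes, the replicate block and the robust prior cannot move a log2 change. Without 1 library the sign of a gene with no overlap cannot turn. Gm10335 and Gm24157 passed where every Vehicle library left was listed at 0. Without 1 library the log2 change ran from -0.23 to 0.30 for Ptger4, -0.38 to 0.23 for Slco2a1, -0.30 to 0.038 for Ccnd1, -0.72 to 0.00738 for Pax7, -0.0375 to 0.31 for Myod1 and -0.57 to 0.22 for Mki67. Mki67 was also at 0.016 after median-ratio scaling and 0.0012 after quantile normalization. Of 503 list values over 17 settings, 54 turned in direction, all of lists that did not pass. Their adjusted p was 0.962 without a filter (interferon, glycolysis, cholesterol synthesis, ribosomal proteins, fibro-adipogenic and pericyte markers; 0.741 for prostaglandin synthesis), 0.969 after median-ratio scaling (G2 and M phase, heat shock, pericyte markers), 0.970 with a filter of 5 TPM (growth factors, pericyte markers; 0.876 for inflammatory cytokines), 0.998 by fry (respiration, cholesterol synthesis, ribosomal proteins) and 0.977 with a mean-variance trend (fibro-adipogenic markers). It was 0.930 for heat shock with a pseudocount of 0.1, and for cholesterol synthesis 0.971 after quantile normalization, 0.973 without mitochondrial genes and 1.00 with the replicate block. Without 1 library the adjusted p of lists that turned ran up to 0.994 from 0.627 for quiescent stem cell genes, 0.650 for the Notch, G2 and M phase and cytokine lists, 0.592 for interferon and Wnt, 0.606 for growth factors, 0.568 for respiration, 0.668 for cholesterol synthesis, 0.00674 for mitochondrial transcripts (without PGE2 1), 0.927 for endothelial, 0.604 for leukocyte and 0.613 for glial markers. It ran up to 0.987 from 0.739 for PGE2 receptors, 0.614 for prostaglandin synthesis, 0.668 for matrix genes, 0.650 for glycolysis and pericyte markers, 0.485 for ribosomal proteins and 0.791 for heat shock, and from 0.612 to 0.977 for fibro-adipogenic markers. Unknown depth and the spread between PGE2 libraries limit what single genes can show: the median 95% confidence interval reached 1.21 on the log2 scale to either side.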

Other observations

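By the rule added after the values were seen (unadjusted p under 0.05, a mean of 5 TPM or more, no overlap), 52 protein-coding genes had higher and 90 had lower values with PGE2, none past the adjusted threshold. Over all tested genes, 3.63% had such a limma p, where chance gives 5%, and 8.01% had no overlap, where chance gives 10%. The median log2 change of all genes was -0.07, on the side of the larger count. No chance share was computed for the genes this rule takes. Among the 10 with the largest positive log2 change were B3gnt2, a glycosyltransferase listed at 0 in Vehicle with 1.49, 17.2 and 18.7 TPM in PGE2, Cog2, a Golgi tethering subunit (1.93, 1.71 and 1.52 against 8.58, 19.3 and 5.80 TPM), and Sdhaf4, an assembly factor of succinate dehydrogenase (4.23, 1.80 and 1.69 against 24.2, 11.6 and 6.70 TPM). Further ones were Gdap1, Tlcd2, Mcpt8, Etl4, Bloc1s2 and Ppp1r21, with log2 changes from 1.84 to 2.16. Since the rule takes genes without overlap, leaving out 1 library cannot turn their direction. Their size could shift: Mcpt8 was at 1.32 without Vehicle 1 and Bloc1s2 at 1.11 without Vehicle 3.

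Among the 10 with the largest negative log2 change, besides Tceanc2 and Lef1, Atg10, an enzyme of autophagosome formation, read 13.4, 26.6 and 16.8 TPM in Vehicle and 2.39, 3.07 and 1.79 TPM in PGE2. Sec61a2, a translocon subunit, read 28.6, 24.4 and 41.5 against 16.7, 0 and 3.42 TPM, and Plscr1, a phospholipid scramblase, 28.3, 21.7 and 18.8 against 12.4, 2.32 and 6.37 TPM. The others were Uap1l1, Cetn4, Rad9b, Nhlrc3 and Emx2, with log2 changes from -3.30 to -1.73.

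Of the tests below, the 3 on mitochondrial genes were chosen after the result was seen.

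mt-Atp6 and mt-Co2 had higher values with PGE2. A rise of the whole mitochondrial genome as large as theirs is argued against by the other 11 mitochondrial mRNAs. Their median log2 change was -0.0489 with an SD of 0.707 (0.195 without mt-Co3), below the smaller of the 2 changes (1.72). The comparison does not decide on a smaller rise. Summed with their copies the 2 genes changed by 0.07 and 0.15. The mitochondrial list passed camera upward without PGE2 1 (adjusted p = 0.00674, preset correlation). Reads shared with nuclear copies are a candidate explanation: Gm10925, Gm28661 and Gm28437 on chromosome 1 match mt-Atp6, mt-Co2 and mt-Co3 without a mismatch over 678, 681 and 783 bases. For mt-Co2 it may hold in part: its copy Gm28661 read 4548, 3743 and 4237 TPM in Vehicle and 0, 1316 and 4109 TPM in PGE2, and the sum of both kept at most 0.238 of the log2 change of mt-Co2, without PGE2 1. For mt-Atp6 it stays open: its copy Gm10925 read 7372, 7858 and 7320 TPM in Vehicle and 155, 7914 and 8195 TPM in PGE2, so it was lower only in PGE2 1, without which the sum kept 0.259 of the log2 change. In PGE2 2 and PGE2 3 the sum lay above every Vehicle library for both genes.

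The cAMP and CREB list passed camera upward with PGE2 (16 of 24 members higher), a call lost in camera's setting with an estimated correlation (p = 0.0293, adjusted p = 0.48). The estimate (0.0019) was below the preset 0.01, so a higher correlation of the members was not what raised this p. Camera uses fewer degrees of freedom in that setting. At the preset correlation, Nr4a2 alone as the whole source is argued against by camera over the other members (23 genes), with an unadjusted p of 0.00898 (bound set at 0.05). This p was not adjusted over the lists, so it does not show that the list would pass the threshold without Nr4a2. At the same correlation, a single library as the whole source is argued against, narrowly, by the fits without 1 library. Their highest camera p was 0.0448, without Vehicle 1 (bound set at 0.05), although the adjusted p passed the threshold only without Vehicle 3. Neither check was run with an estimated correlation, so neither speaks for the setting in which the call was lost. Of the 10 splits of the 6 libraries 1, the real one, gave a camera p as small (0.00221, against 0.0525 as the nearest other), and 10 splits are too few for a share under 0.05. A response to PGE2 stays open as a hypothesis that these data do not settle.

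The differentiation list passed camera downward with PGE2 (13 of 17 members lower, 4 higher), a call lost with an estimated correlation (0.034, p = 0.0556, adjusted p = 0.48). Genes near 0 as the whole source are argued against by the 9 members with a mean of 5 TPM or more. All had lower fitted values, with an unadjusted camera p of 0.00842 at the preset correlation. This p was not adjusted over the lists, so it does not show that these members alone would pass the threshold. Whether a single library carries the list cannot be told apart from a group difference: the highest camera p was 0.0625, without PGE2 1, where fewer libraries were also left. Of the 10 splits 1, the real one, gave a camera p as small (0.00202, against 0.00941 as the nearest other), and 10 splits are too few for a share under 0.05. A delay of differentiation with PGE2 stays open as a hypothesis that these data do not decide.

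For the counts too, 10 splits are too few for a share under 0.05. The real split gave 0 genes past the adjusted threshold by limma, which any split reaches, and the highest other gave 7. Of the 10 splits, 8 gave as many at an unadjusted p under 0.05 (464, with 983 as the highest other), and 3 gave as many lists (2, with 2 as the highest other). Besides the real split, 2 lists passed on grouping Vehicle 1 and PGE2 1 with Vehicle 2 or with Vehicle 3. A call of 1 list came from grouping Vehicle 1 and PGE2 2 with Vehicle 2, PGE2 1 or PGE2 3. The remaining splits gave 0 lists, so most splits other than the real one called a list. The split with 983 sets Vehicle 1, PGE2 2 and PGE2 3 against Vehicle 2, Vehicle 3 and PGE2 1 and gave 0 genes past the adjusted threshold by limma.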
